A study of Homo sapiens with 4 samples.

How the data were processed

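RNA immunoprecipitates from WS1 fibroblasts were made with an ELAVL1 antibody or IgG, per the labels' protocols. RNA was extracted with Trizol and libraries were made with the TruSeq Stranded Total RNA kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, Bowtie2 (without a version) and the genome build hg19, without giving their roles. The peak names in the files show MACS as the peak caller, whose version is not given in the sources used here. The deposited lists' names carry 1e-06, the p at the lowest score, and further settings whose meaning is not stated. Each dose had 1 ELAVL1 and 1 IgG library, grouped by the labels, and the deposited lists are named as comparisons of that pair, so no replicates were pooled.

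The deposited lists give a chromosome, start, end, name and score per peak, and the score is the authors' value for that peak. The lowest score was 60, which as 10 times the negative log10 of p is a p of 1e-06, and 2481 peaks at 0 Gy and 2000 at 5 Gy had exactly 3100, taken here as the value written for a p that underflows. Scores were used to describe, rank or filter peaks within a list and, in the closing observations, to work out tag numbers. The last peaks on chromosome 1 end at 249212761 and 249212698, past the end of that chromosome in GRCh38, so the human annotation at hand, of GRCh38, was not used and no coordinates were converted. Gene assignment, shares by gene region, the gene lists fixed before the data were examined and motif density were therefore not run. Peaks were used as listed, with no filter. Contigs other than chromosomes 1 to 22 and X entered the totals and are not shown. The number of reads per library is unknown, which leaves the precision of single peaks unknown except where the score itself allowed tag numbers to be worked out. A peak against IgG can also move with the abundance of the RNA, and no library of unprecipitated RNA was analysed here.

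Overlap of at least 1 bp was counted with bedtools 2.31.1 and with an array search that gave the same counts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Shares carry 95% Wilson intervals, ratios of peak numbers carry those of the 5 Gy share of all peaks written as a ratio, and medians carry 95% order-statistic intervals. Peaks are not independent, so all intervals cover counting error only and say nothing of variation between cultures. Chance overlap was the median of 100 random placements of the other list on the same chromosomes. With no gene names, the regions named were, by a rule fixed before the data were examined, the 10 shared peaks whose worse rank by score was best and the 8 highest-scoring peaks of each dose without an overlapping peak at the other. Alternatives were a score of at least 100, a reciprocal overlap of 50%, a distance of 500 bp, equal numbers of top peaks, merging of neighbouring peaks and leaving out contigs other than chromosomes 1 to 22 and X.

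Tag numbers were worked out from scores below 1000 by asking for which whole number k the score equals 10 times the negative log10 of the Poisson probability of more than k tags, given a uniform rate over the larger of the peak's width and a scan window. A match was counted within 0.012 of the score, and the window (from 200 to 300 bp) and rate were those that matched the most peaks. The search and the overlap counting were tested on simulated data. On 47868 simulated peaks with the 0 Gy widths, a window of 220 bp and a rate of 6.6 tags per kb were recovered, and 99.996% of the peaks made at that rate were matched, against 0.328% of peaks made at higher rates. On 36174 with the 5 Gy widths, a window of 270 bp and a rate of 6.1 tags per kb were recovered.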

Results

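RNA recovered with an ELAVL1 antibody was compared between irradiated and unirradiated WS1 cells, which are human skin fibroblasts. ELAVL1, also called HuR, is an RNA-binding protein that recognises U-rich and AU-rich stretches and is known to stabilise many of the mRNAs it binds. In RNA immunoprecipitation sequencing (RIP-seq), RNA recovered with an antibody against a protein is sequenced beside RNA recovered with a nonspecific IgG, and regions with more reads in the first are called as peaks. The 4 libraries were 1 ELAVL1 precipitate and 1 IgG precipitate from cells at 0 Gy, and 1 of each from cells harvested 24 h after a single X-ray dose of 5 Gy. The values analysed here were 2 lists of peaks, 1 per dose, each calling the ELAVL1 library against the IgG library of its own dose. With a single library pair per dose, a difference between the lists has no replicate check, so no p-value is given, and every interval below covers counting error only. Read totals per library were not given in the sources used here. The peaks carry a position and a score but no strand and no gene, and no annotation of their genome build (hg19) was at hand, so regions are named by hg19 position alone and their place in exons, introns or UTRs was not analysed here.

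The first question was how many peaks were listed at each dose. A peak marks RNA recovered with the antibody, and no contact sites of ELAVL1 were mapped. The 0 Gy list held 47930 peaks and the 5 Gy list 36216, a ratio of 0.756 (95% Wilson interval 0.745 to 0.766). Each of chromosomes 1 to 22 and X had fewer peaks at 5 Gy, with ratios from 0.713 on chromosome 20 to 0.793 on chromosome 14. For all 23 chromosomes the interval held the overall ratio, so the lower number was spread over the genome and not set by a few chromosomes. Covered length differed less than peak number. The 0 Gy peaks covered 37.9 Mb and the 5 Gy peaks 34.7 Mb, a ratio of 0.917, and 25.6 Mb was covered at both doses.

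**Figure D1:**
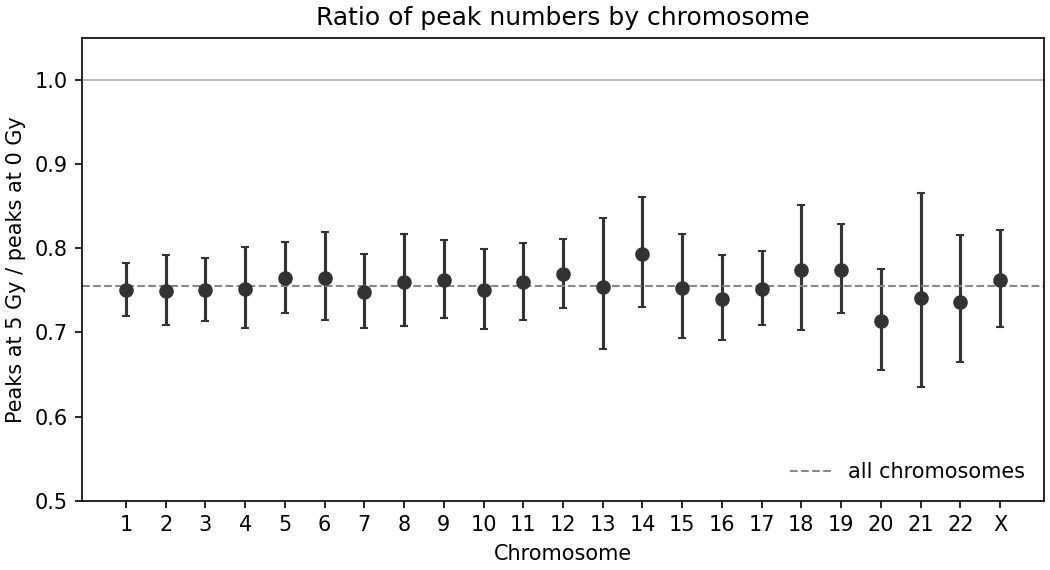
The number of peaks at 5 Gy divided by the number at 0 Gy (y axis, starting at 0.5) for each chromosome (x axis), with 95% Wilson intervals as bars, the overall ratio of 0.756 as a dashed line and equal numbers as a solid line. All 23 points lie below 1, between 0.713 and 0.793.

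Peaks were narrower in the unirradiated list. The median width was 448 bp at 0 Gy (95% order-statistic interval 445 to 452) and 559 bp at 5 Gy (554 to 563), with quartiles of 332 and 782 bp against 389 and 1001 bp. Peaks from 300 to 400 bp wide made up 26.0% of the 0 Gy list and 15.7% of the 5 Gy list. The widest peak of each list lay in the same place on chromosome 19, from 57801817 to 57819073 at 0 Gy (17257 bp) and from 57801966 to 57819992 at 5 Gy (18027 bp).

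**Figure D2:**
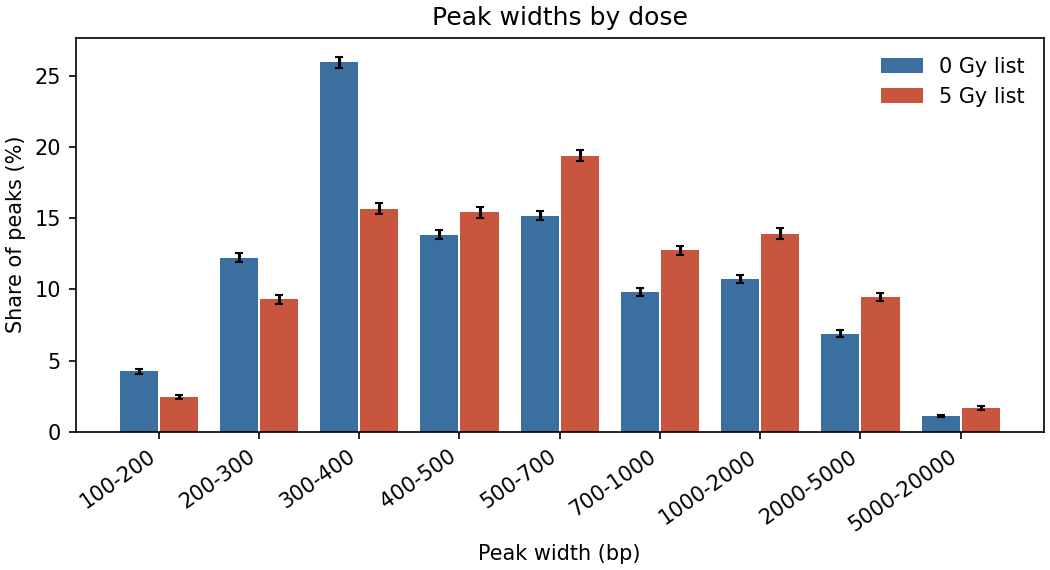
The share of each list's peaks (y axis, %) in 9 classes of peak width (x axis, bp), blue for 0 Gy and red for 5 Gy, with 95% Wilson intervals as bars. The class from 300 to 400 bp holds 26.0% of the 0 Gy peaks and 15.7% of the 5 Gy peaks, and every class above 400 bp holds a larger share at 5 Gy.

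The second question was which peaks the doses shared. Of the 0 Gy peaks, 27866 of 47930 (58.1%, 95% Wilson interval 57.7% to 58.6%) overlapped a 5 Gy peak by at least 1 bp. Of the 5 Gy peaks, 26431 of 36216 (73.0%, 72.5% to 73.4%) overlapped a 0 Gy peak. Placing the other list at random on the same chromosomes gave medians of 2.35% and 3.08% over 100 placements. Random placement within 50 kb of each peak, which stays near transcribed regions and was chosen after the data were examined, gave 12.7% and 16.2%. A reciprocal overlap of 50% lowered the shares to 41.9% and 55.4%. The order of the shares followed the lengths of the lists, since the numbers of overlapping peaks were close (27866 and 26431). With equal numbers of top-scoring peaks (the size of the shorter list) the shares were 68.3% at 0 Gy and 67.0% at 5 Gy. Lists of equal length give near-equal shares where most overlaps are one to one, so these values do not test a difference between doses.

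Peaks that overlapped a peak at the other dose had the higher median score in each list. The score is the authors' own and is compared here only within a list. Within the 0 Gy list the median score was 259.5 (254.0 to 264.6) for peaks that overlapped a 5 Gy peak and 87.4 (86.9 to 88.2) for the 20064 that did not. Within the 5 Gy list the medians were 212.9 (208.9 to 216.2) and 82.4 (81.5 to 83.2), the latter over 9785 peaks. Of the 0 Gy peaks without a partner, 61.1% scored below 100, against 17.8% of those with one. The corresponding shares at 5 Gy were 67.0% and 21.6%. Overlap rose with score without a break. In the 0 Gy list it went from 26.6% for scores of 60 to 80 to 99.8% for scores of 3100 or more, and in the 5 Gy list from 42.6% to 99.95%. Overlapping peaks were also wider than the others, with median widths of 591 against 359 bp at 0 Gy and 655 against 421 bp at 5 Gy. Score and width were not separated. A score of exactly 3100, held by 2481 peaks at 0 Gy and 2000 at 5 Gy, was taken as the value written for a p too small to compute. On that reading these peaks are stronger than the few scored above 3100, and peaks of 3100 or more (2566 and 2070) are not ordered by their score.

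**Figure D3:**
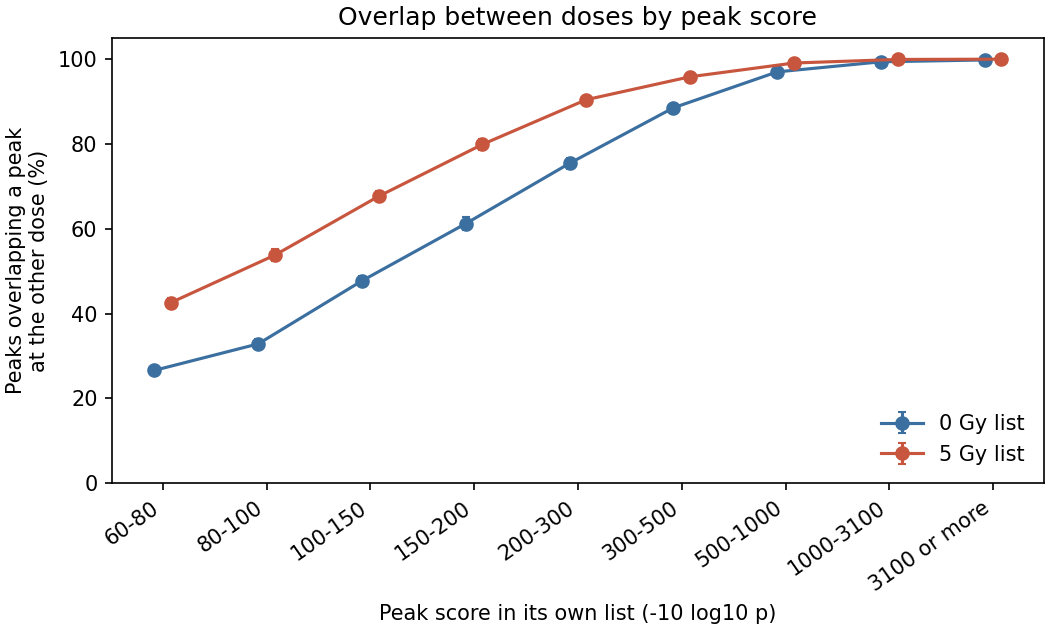
The share of peaks that overlap a peak at the other dose (y axis, %) by the peak's score in its own list (x axis, 9 classes, 10 times the negative log10 of p), blue for the 0 Gy list and red for the 5 Gy list, with 95% Wilson intervals as bars. The share rises from 26.6% to 99.8% in the 0 Gy list and from 42.6% to 99.95% in the 5 Gy list.

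The 10 shared regions named by rank of the deposited score overlapped along most of their length, with 1 exception. The 0 Gy peak of each had a score above 3100, which on the reading above is weaker than a score of exactly 3100. These are therefore examples from the class of 3100 or more and not its strongest members. On chromosome X the region from 15337579 to 15339946 at 0 Gy (score 3179.53) lay inside a 5 Gy peak from 15337562 to 15340083 (score 3210.86). On chromosome 8 the 0 Gy peak from 82613343 to 82615448 lay inside the 5 Gy peak from 82613196 to 82615532. The region on chromosome 1 from 17764534 to 17765334 was the narrowest by its 5 Gy width, at 801 bp and 873 bp. Chromosome 12 held 3 of the 10, starting at 50868826 (4983 bp at 0 Gy, 5304 bp at 5 Gy), 77244613 (3072 and 3129 bp) and 122902095 (5192 and 5247 bp). The widest lay on chromosome 16 from 15005280 to 15010848 (5569 bp at 0 Gy, 5584 bp at 5 Gy). The remaining regions started at 23727951 on chromosome 10 and 64193737 on chromosome 14, and at 39885571 on chromosome 15. The last was the exception, since its 0 Gy peak of 536 bp and its 5 Gy peak of 1234 bp shared 368 bp.

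Some strong peaks were listed at 0 Gy alone. The highest deposited score among them, 3142.94, belonged to a 4847 bp peak on chromosome 17 from 28791563 to 28796409, whose nearest 5 Gy peak lay 9436 bp away. A second region on chromosome 17, from 75088999 to 75091107, had its nearest 5 Gy peak 27657 bp away. Neighbouring peaks on chromosome 6, from 36562108 to 36569300 and from 36569512 to 36572045, together formed a stretch with the nearest 5 Gy peak 49208 bp from the first. The 8896 bp peak on chromosome 5 from 14369419 to 14378314 had none within 10 kb. The second chromosome 17 peak, the neighbouring chromosome 6 peaks, the chromosome 5 peak and a peak on chromosome 10 from 71926778 to 71930331 had the score of 3100. The chromosome 10 peak and its neighbour from 71922345 to 71925090 (score 1871.21) had 5 Gy peaks 117 and 419 bp away, so they were unlisted by position more than by region. The last of the 8 was a 774 bp peak on chromosome 6 from 26158336 to 26159109 (score 1775.22). In all, 6 of 2566 peaks scored 3100 or more at 0 Gy lacked a 5 Gy peak.

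Other peaks were listed at 5 Gy alone. A single one scored 3100, a 4126 bp peak on chromosome 20 from 31442601 to 31446726, with its nearest 0 Gy peak 11036 bp away. The next, on chromosome 10 from 95660480 to 95662334, scored 1179.28. The peaks on chromosome X from 68060074 to 68061971 (score 1035.81) and on chromosome 4 from 122615267 to 122617306 (score 1012.85) had 0 Gy peaks 1311 and 1112 bp away. The most isolated was the 3255 bp peak on chromosome 2 from 14774062 to 14777316 (score 850.92), 897352 bp from any 0 Gy peak. The others lay on chromosome 11 from 88067219 to 88070390, on chromosome 9 from 19102213 to 19102951 and on chromosome 20 from 3874271 to 3875966, each with 3 or more 0 Gy peaks within 10 kb. Of the 8 regions per dose, 6 at 0 Gy and 6 at 5 Gy had no peak of the other dose within 500 bp.

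Peaks of both lists were also joined into clusters wherever gaps were at most 10 kb, a stand-in for genes chosen after the data were examined. Of 15970 clusters, 10958 (68.6%) held peaks of both doses, 3409 of 0 Gy alone and 1603 of 5 Gy alone. Most clusters of a single dose were single peaks (2595 at 0 Gy and 1398 at 5 Gy), and 814 and 205 had 2 or more. Clusters with both doses held 90.4% of the 0 Gy peaks and 94.8% of the 5 Gy peaks. Of the peaks with no overlapping partner, 73.9% at 0 Gy and 79.8% at 5 Gy had a peak of the other dose within 10 kb. No value for random placement is given for these shares or for the cluster shares. Peaks lie close together, so these shares do not show agreement beyond chance. Among clusters with both doses, 4595 had more 0 Gy peaks, 1565 more 5 Gy peaks and 4798 equal numbers. On autosomes the greatest excess at 0 Gy was on chromosome 1 from 164528312 to 164623026, with 38 peaks at 0 Gy and 8 at 5 Gy. Next came chromosome 20 from 30946796 to 31035406, with 46 and 21. The greatest autosomal excess at 5 Gy was on chromosome 12 from 109071402 to 109124446, with 10 peaks at 0 Gy and 22 at 5 Gy. It was followed by 3 clusters with an equal excess of 7, on chromosome 16 from 84492305 to 84537874 (13 and 20 peaks) and on chromosome 12 from 95867677 to 95896567 (6 and 13) and from 96775802 to 96794571 (2 and 9). The largest autosomal clusters of 0 Gy alone had 8 peaks, for example on chromosome 11 from 57405864 to 57414853 and on chromosome 9 from 128511647 to 128524950. The largest autosomal clusters of 5 Gy alone had 6, on chromosome 20 from 1391355 to 1398211 and on chromosome 5 from 141697335 to 141704583. These regions were picked as extremes of many clusters, and peak numbers depend on how a caller divides a broad signal.

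**Figure D4:**
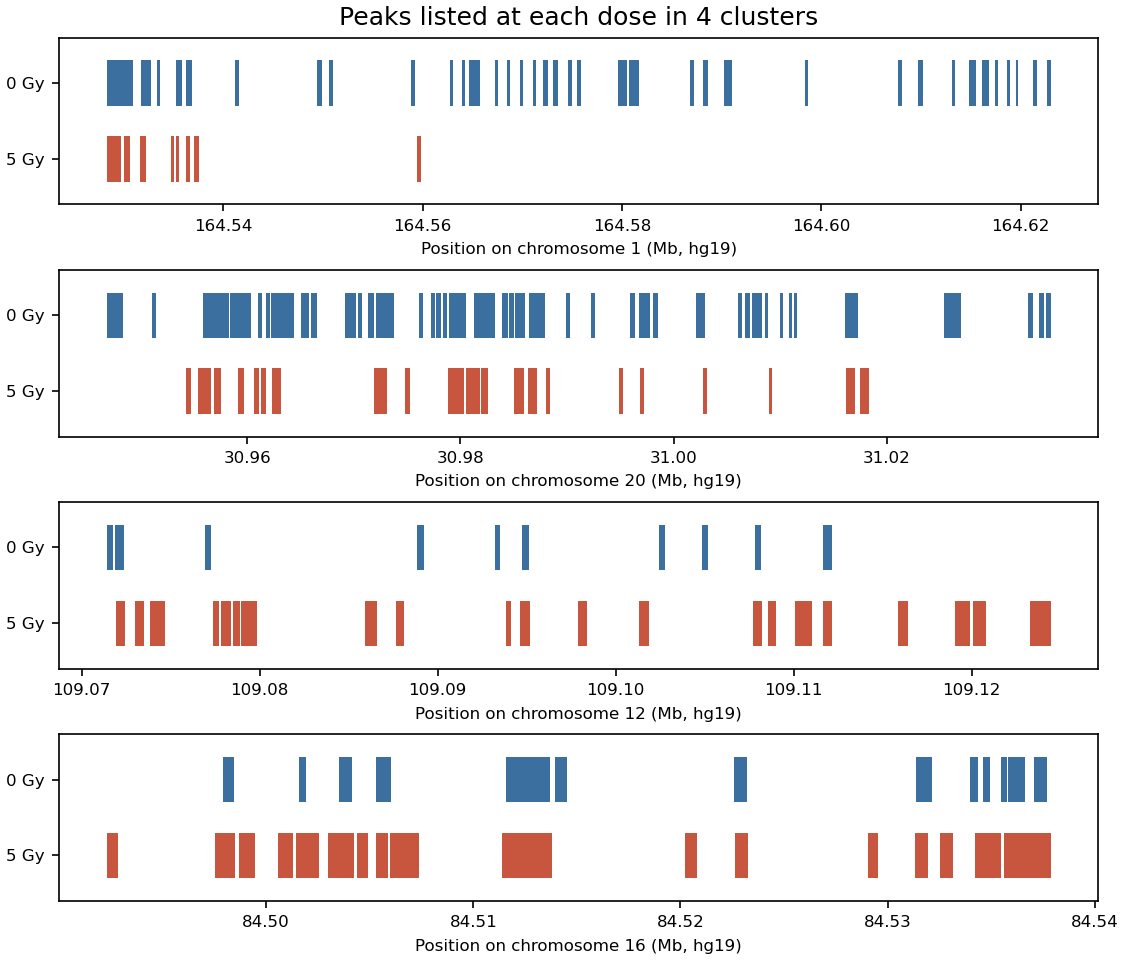
Peaks at 0 Gy (blue, upper row) and 5 Gy (red, lower row) in 4 clusters on chromosomes 1, 20, 12 and 16, drawn to scale against hg19 position in Mb (x axis). On autosomes, the upper pair had the greatest excess of 0 Gy peaks (38 against 8 and 46 against 21) and the third the greatest excess of 5 Gy peaks (22 against 10). The last (20 against 13) was 1 of 3 autosomal clusters tied next.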

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

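Merging within 500 or 1000 bp, covered length and clusters were chosen after the data were examined. Of 52 alternative values 32 moved. A count was called moved when it changed by more than 1.5-fold, and other values when they left their interval or range. Those intervals cover counting error only and are narrow, so small changes also count as moves. Some directions were fixed by the setting. A stricter overlap can only lower an overlap share, a wider distance can only raise it, and a score minimum can only lower peak numbers. The ratio of peak numbers stayed below 1 in all 6 alternatives: 0.780 at a score of at least 100, 0.790 and 0.814 after merging within 500 and 1000 bp, and 0.917 for covered length. A score of at least 100 left 30702 peaks at 0 Gy and 23940 at 5 Gy, and merging within 1000 bp left 31401 at 0 Gy. The overlap shares at 0 Gy and 5 Gy were 41.9% and 55.4% at a reciprocal overlap of 50%, 64.1% and 78.9% at a score of at least 100 in both lists, 74.6% and 86.5% with that minimum in the list asked about, 68.3% and 67.0% for as many top peaks as the shorter list, 84.0% and 83.6% for the top 5000, and 66.5% and 80.05% within 500 bp. So the higher share at 5 Gy turned over, by a small margin, for equal numbers of top peaks, where equal list lengths by themselves give near-equal shares. Median scores of overlapping peaks were 347.6 and 254.9 at a reciprocal overlap of 50% and 214.0 and 188.2 within 500 bp, and those of the others 95.5 and 94.7 at 50% and, at 0 Gy, 86.6 within 500 bp. Clusters of 0 Gy alone numbered 5176 at a gap of 5 kb and 2116 at 20 kb, and those of 5 Gy alone 1036 at 20 kb. For the other moves the cause was not tested. No paired analysis was possible because each group has 1 library. Alternatives for genes, gene regions, gene lists and motifs were not run, since no hg19 annotation or sequence was at hand. Depth limits weak peaks most, and read totals are unknown.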

Other observations

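The tests of strong single-dose peaks, the comparison of list-wide widths and the reading of tag numbers from scores were chosen after the data had been examined. Scores of 54.2% of the 0 Gy peaks below 1000 (22783 peaks) and 51.4% of the 5 Gy peaks (16192) equalled a Poisson score at 1 uniform rate. At most 3.70% and 4.36% did when the window was changed by 10 or 20 bp. Most peaks were wider than the window, so a fall of that size means that the rate per bp changed too. The contrast therefore tests window and rate together and not the window alone. The rates were 7.02 tags per kb over a 234 bp window at 0 Gy and 5.79 over a 260 bp window at 5 Gy. In that window 11 tags at 0 Gy and 10 at 5 Gy reached the threshold, and the median matched peak held 18 tags at either dose. Matching favoured peaks without a partner at the other dose, since among peaks with scores below 1000 66.9% of those and 42.6% of the overlapping peaks were matched at 0 Gy, and 68.3% and 43.8% at 5 Gy.

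For the lower number of peaks at 5 Gy, fusion of neighbouring peaks as the sole cause was argued against, since the ratio was still 0.790 after merging within 500 bp in both lists, below a bound of 0.9 set before that ratio was computed, and clusters of 0 Gy alone outnumbered those of 5 Gy alone by 3409 to 1603. Some fusion stays open, since the ratio was 0.814 after merging within 1000 bp and 0.917 for covered length, and 9.28% of 5 Gy peaks overlapped 2 or more 0 Gy peaks against 4.79% in reverse. The uniform rate at 5 Gy was 0.825 of that at 0 Gy. In the thinning and sampling tests below, this fitted rate was assumed to stand for depth, since read totals are unknown. After thinning to the 5 Gy rate, 80.7% of the matched 0 Gy peaks still reached the 5 Gy threshold. That share lay between bounds set before it was computed (at most 80% if depth was the cause, at least 90% if not). Of the matched 0 Gy peaks 41.2% overlapped a 5 Gy peak (45.6% of those left by thinning), where Poisson sampling at the 5 Gy depth would list a mean of 74.1%. In reverse, 58.8% of the matched 5 Gy peaks overlapped a 0 Gy peak, where sampling at the 0 Gy depth would list a mean of 89.2%. Both means take the observed tag numbers as true rates, although these peaks were listed because they passed the threshold. The means can therefore be too high, and no conclusion on depth is drawn from either gap. Depth stays open as a cause of the difference in number, which does not depend on which peaks are listed, and irradiation, with 1 library pair per dose, cannot be told apart from it.

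Of 3490 matched 0 Gy peaks that Poisson sampling would miss at the 5 Gy depth with a probability of at most 0.001, 524 (15.0%) had no 5 Gy peak, and of 4423 such 5 Gy peaks 511 (11.6%) had no 0 Gy peak. These shares are for matched peaks and were not computed for the rest. Sampling of independent tags gives fewer, 0.389 of the 3490 from the observed tag numbers, and a median of 11 and at most 19 of about 3752 such peaks in 100 redraws at unchanged rates. Whether tags are independent is unknown and each dose has 1 precipitate, so sampling, variation between precipitates, local IgG signal and a response to irradiation cannot be told apart. A 5 Gy peak lay within 500 bp for 26.3% of the 524, which argues against shifted edges as the general cause.

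As to the wider peaks at 5 Gy and the longer scan window, over 19750 peaks that overlapped one to one, the 5 Gy peak was wider by a median of 22 bp (20 to 23) and wider in 58.3% of pairs. The windows differ by 26 bp, so the window stays open for these pairs, but peaks that did not widen would also pass this test and overlaps of more than 1 peak are left out. The medians of the whole lists differed by 111 bp, more than the 26 bp between the windows. How far a longer window can widen peaks by joining neighbouring signal was not measured, so this does not exclude the window. The difference in median width was present among overlapping peaks (591 bp at 0 Gy and 655 bp at 5 Gy) and among the others (359 and 421 bp), so it does not come from the mix of these classes alone. How broad signal was divided into peaks was not tested.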
